A study of Canis lupus familiaris with 12 samples.

How the data were processed

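RNA was sequenced from left ventricle and mitral valve of dogs with degenerative mitral valve disease (DMVD) and of control dogs, 12 libraries from 8 dogs, in 4 groups by tissue and diagnosis. Groups, breeds and ages were taken from the labels. Per the labels, RNA was extracted with a kit for fibrous tissue, made into TruSeq libraries and sequenced on an Illumina HiSeq instrument. The submitters' processing notes name cutadapt, Bowtie and TopHat and the genome build CanFam3.1, without versions; the program that made the gene values is not given in the sources used here.

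The authors deposited one gene table per tissue with 24223 genes each, under the same gene identifiers. Per the file headers, each table holds one value per group in columns laid out like a Cuffdiff gene table, read here as FPKM, fragments normalised to gene length and library size, as deposited by the authors. The authors' deposited log2 fold change is control over DMVD, with a placeholder where a group is listed at 0. The authors' deposited test statistic is a score whose sign is opposite to that log2 fold change. The authors' deposited p-value is not adjusted for the number of genes. A status column marks the genes the authors tested: 13788 in the left ventricle and 14810 in the mitral valve. No values per library were used, so no spread between dogs could be computed and the depth of each library is unknown.

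Log2 fold changes were recomputed as DMVD over control from the group values. For tested genes above 0 in both groups the p-value equals the two-sided normal p of the statistic, with a largest gap of 2.84e-06 in the left ventricle and 2.64e-06 in the mitral valve. An SE was therefore taken as the size of the log2 fold change divided by the statistic. It is the authors' model error on group values and has no count of replicates of its own. Its median was 0.47 in the left ventricle and 0.52 in the mitral valve for genes with a mean of at least 5 FPKM, and 0.82 and 1.11 for genes with a mean under 1 FPKM. The authors' p-values were adjusted here by Benjamini-Hochberg over the tested genes of each tissue, at 0.05. A group listed at 0 gives no fold change; 337 tested genes of the left ventricle and 333 of the mitral valve had one, and they kept their p. For these genes the statistic used in cameraPR was the normal score of that p, signed by the group that was higher.

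The fits planned before the data were examined needed counts or values per library, and the plan foresaw values without a test where the tables hold group values. The authors' own test was used in their place, a choice made after the tables were seen. The groups, the gene lists, the rule for named genes, the preset correlation and the threshold were set before the data were examined. The joint fit of both tissues and the test of valve against ventricle in control dogs were not run because the tables were normalised separately. The DMVD effects of the tissues were instead compared gene by gene, valve minus ventricle, divided by the root of the summed squared SE, with a two-sided normal p and Benjamini-Hochberg over 13099 genes. That test was also chosen after the tables were seen. Calls shared by the tissues were compared with Fisher's exact test over genes tested in both. Control values were set side by side as log2 ratios, with the median of all genes above 1 FPKM in both given as the shift.

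Gene symbols came from the tables. Of the gene names, 14575 were used as symbols as they stand, 76 UniProt entry names were translated and 733 UniProt names were left untranslated. Another 3160 were small RNAs or RNA families, and 5580 genes had no name. A symbol that stood on more than 1 gene was carried by 74 genes, and 25 genes had a spreadsheet date as their name. A total of 6516 genes share their listed locus with another gene, and the locus is then the span of all of them. Positions are on CanFam3.1 and counted from 1.

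The 44 gene lists held 977 genes, of which 739 matched a symbol in the tables. Lists with at least 3 tested members were tested on the authors' statistic with cameraPR of limma 3.58.1 under R 4.3.3, with a preset inter-gene correlation of 0.01, two-sided, Benjamini-Hochberg over the lists of a tissue. An estimated correlation could not be had without values per library. The list p-values therefore rest on the preset correlation and do not measure agreement between dogs. Each list's median was also placed among 10000 random lists drawn from 20 bins of mean expression, which ignores any correlation between genes. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

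Named genes were, in each tissue, the 10 largest changes in each direction among genes past 0.05 with a symbol and a mean of at least 5 FPKM, up to 4 members with the smallest p of each list named, and 19 genes fixed for the study question. The rule also asked for every DMVD library above or below every control library, which group values do not show. Some genes that meet the rule are not reported here. For the difference between tissues the rule took up to 5 genes per direction, with the mean over the 4 group values. Of the 19 fixed genes 10 matched a symbol in the tables and 9 were tested in each tissue; HTR2B, TPH1, TGFB1, TGFB2, MMP2, TIMP1, NOS3, AGTR1 and ACE were not matched and are not analysed here. A locus named COL3A1 on chromosome 11 was untested in both tissues, at 0.344 against 0.0809 FPKM in the left ventricle and 0.449 against 0.455 FPKM in the mitral valve, DMVD against control, in the authors' deposited table.

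The alternatives were a pseudocount of 1 or of 0.1 on the FPKM, no filter on low values, and, chosen after the tables were seen, a mean of at least 1 FPKM, recentring on the median log2 fold change, leaving out genes that share a locus, the mitochondrial genome or genes listed at 0 in a group, thresholds of 0.01 and 0.1 (planned for the overlap), preset correlations of 0.05 and 0.1, and ranks in place of the statistic. The steps were tested on simulated data with the same SE and independent normal errors, without correlation between genes or between tissues. The rates that follow check the steps under that setting and are not error rates of these data. Of simulated log2 changes of 1, 2, 3 and 4, 7.0%, 58.2%, 81.8% and 90.9% were recovered in the left ventricle and 2.0%, 29.4%, 72.2% and 86.7% in the mitral valve, with 8.9% and 7.8% of calls false. A simulated difference of 4 between tissues was recovered in 75.5% of cases with 3.8% of calls false, and in each tissue the 1 list shifted was called and 0 others.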

Results

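Gene expression was measured by RNA sequencing in the hearts of dogs with degenerative mitral valve disease (DMVD), a thickening of the valve leaflets that lets blood leak back into the left atrium, and of control dogs. The series holds 12 libraries from 8 dogs, 4 with DMVD and 4 controls. The left ventricle gave 6 libraries, 2 DMVD and 4 control, and the mitral valve gave 6 libraries, 3 DMVD and 3 control. Both tissues came from 3 of the control dogs and 1 of the DMVD dogs. The DMVD ventricle samples came from a Jack Russell Terrier of 5 years and a Pomeranian of 9 years, and the DMVD valve samples from the same Pomeranian and a pair of Beagles of 16 and 17 years. The controls were a Beagle of 8 years and Hound mixes of 3 years. The values are group values, one per diagnosis and tissue, so no spread between dogs could be shown and the depth per library is unknown. Of the 24223 genes listed for each tissue, 13788 were tested in the left ventricle and 14810 in the mitral valve. Every log2 fold change below is DMVD over control, and the error after ± is the standard error (SE) implied by the authors' own test statistic.

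The left ventricle comparison asks how the main pumping chamber differs when the mitral valve is diseased. Lists of immediate early genes, of cytokines and chemokines and of erythroid genes rose in the DMVD ventricle samples. The neutrophil chemokine IL8 rose by 7.08 ± 0.67 on the log2 scale (gene ENSCAFG00000003029, chromosome 13, 62434792 to 62438932, CanFam3.1), from a control value of 0.435 FPKM to 58.9 FPKM in the authors' deposited table. The metal-binding metallothionein MT2 (ENSCAFG00000023759, chromosome 2, 59607926 to 59608825) rose by 7.07 ± 0.61, and the long pentraxin PTX3, a soluble pattern-recognition protein, by 5.88 ± 0.53. The alpha-globin gene HBA (ENSCAFG00000029904, chromosome 6, 40326459 to 40329857) rose by 5.86 ± 0.62, to 3559 FPKM against 61.3 in the authors' deposited table. The atrial natriuretic peptide gene NPPA (ENSCAFG00000016539, chromosome 2, 84406205 to 84408369), a marker of ventricular wall stress, rose by 1.95 ± 0.53 (adjusted p = 0.0125).

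Of the 13788 genes tested, 425 passed an adjusted p of 0.05 (Benjamini-Hochberg over the authors' two-sided p), 265 higher and 160 lower in DMVD, and 1552 had an unadjusted p under 0.05. Of these, 134 higher and 38 lower genes had a symbol and a mean of at least 5 FPKM. The 10 largest rises among them also held AHSP, the chaperone of free alpha-globin (6.65 ± 1.21, adjusted p = 9.97e-06), the globin gene HBM (6.40 ± 1.08), the secreted hormone STC1 (5.39 ± 0.51), the anti-apoptotic gene BCL2A1 (5.02 ± 0.63), and the myeloid calcium-binding genes S100A12 (4.90 ± 0.99) and S100A8 (4.65 ± 0.67, adjusted p = 3.03e-09). With 1 FPKM added to both groups, the log2 fold changes were 5.38 for IL8, 5.02 for PTX3, 4.86 for STC1, 4.42 for AHSP, 3.83 for HBM and 3.56 for BCL2A1. They were -4.64 for PCP2, -2.07 for AADAC, -1.98 for SORCS1 and 0.59 for HAS2. The 10 largest falls were led by PCP2 (ENSCAFG00000018302, chromosome 20, 52407779 to 52409628), which fell by 5.60 ± 0.90 (adjusted p = 1.82e-07), from 49.4 to 1.02 FPKM in the authors' deposited table. The others were TCEAL7 (-3.40 ± 0.89), AADAC (-2.69 ± 0.57), SORCS1 (-2.57 ± 0.58), the inhibin alpha subunit INHA (-2.36 ± 0.51) and the secreted phospholipase PLA2G5 (-2.29 ± 0.51). They also held PPP1R1C (-2.29 ± 0.63), the transcription factor TCF15 (-2.24 ± 0.50), the glycerol-3-phosphate dehydrogenase GPD1 (-2.18 ± 0.44) and FAM198B (-2.12 ± 0.43). Among the genes named for the study question in advance, the proteoglycan VCAN rose beside NPPA, by 2.29 ± 0.45 (adjusted p = 5.76e-05). The others did not pass: NPPB had 1.62 ± 0.63 (adjusted p = 0.170), HAS2 1.42 ± 0.57, ADAMTS5 0.85 ± 0.61, COL1A1 0.22 ± 0.45, ACTA2 0.13 ± 0.43, MYH11 -0.50 ± 0.46 and EDN1 0.11 ± 0.64.

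Immediate early, cytokine, macrophage, complement, glucocorticoid-response and hypoxia-response lists rose in the DMVD ventricle. Among the immediate early genes, transcription factors and feedback regulators induced within minutes of a stimulus, 11 of 25 tested members rose, none fell and 14 did not pass; adjusted over the list alone, 19 rose. All 25 had higher DMVD values, with a list median of 1.66 (cameraPR adjusted p = 2.71e-24), and CTGF (2.78 ± 0.45), GADD45B (2.68 ± 0.46), JUNB (2.60 ± 0.45) and FOSL2 (3.01 ± 0.57) had the smallest p. Of 23 cytokine, chemokine and receptor genes 8 rose, none fell and 15 did not pass (10 higher adjusted over the list alone, cameraPR adjusted p = 1.25e-14). The monocyte attractant CCL2 rose by 4.29 ± 0.51, the oncostatin M receptor OSMR by 2.43 ± 0.43 and the interleukin-33 receptor IL1RL1 by 3.38 ± 0.71. Of 14 macrophage and monocyte markers 5 rose, none fell and 9 did not pass (9 higher adjusted over the list alone, cameraPR adjusted p = 1.81e-14), among them S100A9 (4.27 ± 0.58) and the Fc receptor FCGR1A (2.83 ± 0.60). Of 24 complement and coagulation genes 5 rose, none fell and 19 did not pass (7 higher adjusted over the list alone, cameraPR adjusted p = 2.32e-09), with the urokinase receptor PLAUR at 4.11 ± 0.60, VWF at 1.79 ± 0.49, C1QB at 1.57 ± 0.45 and C5AR1 at 3.75 ± 1.13. Of 12 glucocorticoid-response genes 5 rose, none fell and 7 did not pass (6 higher adjusted over the list alone, cameraPR adjusted p = 3.96e-11), including MT2, FKBP5 (1.91 ± 0.45), SGK1 (2.23 ± 0.60) and CRISPLD2 (1.55 ± 0.42). Of 18 hypoxia-response genes 6 rose, none fell and 12 did not pass (7 higher adjusted over the list alone, cameraPR adjusted p = 5.25e-07), with DDIT4 at 3.53 ± 0.54, LOX at 2.49 ± 0.48, HK2 at 2.53 ± 0.56 and BHLHE40 at 1.68 ± 0.42. Blood transcripts moved with all of these lists: of 6 erythroid and haemoglobin genes 4 rose, none fell and 2 did not pass, with a median of 6.13 (5 higher and 1 lower adjusted over the list alone, cameraPR adjusted p = 7.10e-13). That list held HBA, HBM, AHSP and the haem synthesis gene ALAS2 (1.84 ± 0.50). With 1 FPKM added to both groups, the values that moved by more than their SE became 3.49 for S100A9, 3.30 for PLAUR, 2.32 for FOSL2, 2.16 for C5AR1 and 2.11 for FCGR1A. HK2 then had 1.52, IL1RL1 1.27 and ALAS2 1.11.

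Matrix and growth-factor lists were mixed in the ventricle. Of 20 TGF-beta and BMP signalling genes 5 rose, none fell and 15 did not pass (5 higher adjusted over the list alone, cameraPR adjusted p = 2.67e-05), with the activin subunit INHBB at 4.55 ± 0.61, SKIL at 1.40 ± 0.42 and TGFBR2 at 1.37 ± 0.42. Of 23 elastic fibre and glycoprotein genes 4 rose, 1 fell and 18 did not pass (5 higher and 1 lower adjusted over the list alone). THBS1 rose by 4.15 ± 0.48, the collagen and elastin cross-linking enzyme LOX by 2.49 ± 0.48 and POSTN by 3.64 ± 0.99, while FBN2 fell by 2.05 ± 0.44. Its cameraPR adjusted p was 0.000324 at the preset correlation of 0.01 and 0.000122 to 0.0524 over the alternatives, the highest at a correlation of 0.1. Of 10 metalloprotease, ADAMTS and TIMP genes 2 rose, none fell and 8 did not pass (3 higher adjusted over the list alone, cameraPR adjusted p = 0.00738, with adjusted p = 0.00109 to 0.326 over the alternatives, the highest with ranks). They were ADAMTS9 (3.79 ± 0.46) and the neutrophil collagenase MMP8 (7.34 ± 2.06). Of 11 fibrillar and network collagens 1 fell, COL14A1 (-1.42 ± 0.44), none rose and 10 did not pass (1 lower adjusted over the list alone, cameraPR adjusted p = 0.780). Of 20 proteoglycan and hyaluronan genes 3 rose, 1 fell and 16 did not pass (5 higher and 1 lower adjusted over the list alone, cameraPR adjusted p = 0.0790, with adjusted p = 0.00854 to 0.453 over the alternatives, the lowest with a mean of at least 1 FPKM). The hyaluronan synthase HAS1 rose by 5.22 ± 0.99 and HAPLN3 by 1.93 ± 0.59, and SDC1 fell by 2.12 ± 0.63. Of 14 endothelial markers 3 rose, SOX17 (2.28 ± 0.47), ROBO4 (1.68 ± 0.43) and VWF, none fell and 11 did not pass (4 higher adjusted over the list alone, cameraPR adjusted p = 7.71e-05). Of 15 smooth muscle and myofibroblast markers and 13 fibroblast and valve interstitial cell markers 0 passed, also adjusted over the list alone (cameraPR adjusted p = 0.612 and 0.284). Adding 1 FPKM to both groups brought MMP8 to 1.30, from values of 1.48 FPKM in DMVD and 0.00912 in control in the authors' deposited table. Other values that moved by more than their SE became 3.56 for THBS1, 2.96 for ADAMTS9, 2.19 for both POSTN and HAS1, 1.65 for LOX and 1.27 for HAPLN3. SDC1 then had -0.84 and COL14A1 -0.98.

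Few heart muscle and energy metabolism genes of the ventricle passed. Of 14 cardiomyocyte markers 0 passed, also adjusted over the list alone, with a median of -0.19 (cameraPR adjusted p = 0.655), and MYL3, the ventricular essential light chain, had -0.07 ± 0.67. None of 30 nuclear subunits of oxidative phosphorylation (median -0.02) and none of 17 tricarboxylic acid cycle genes (median -0.29) passed either, over all genes or adjusted over the list alone (cameraPR adjusted p = 0.880 and 0.606). Of 26 fatty acid oxidation genes 2 fell, MLYCD (-1.42 ± 0.42) and ACSL1 (-1.57 ± 0.49), none rose and 24 did not pass (2 lower adjusted over the list alone, cameraPR adjusted p = 0.450). Of 13 glycolysis and glucose uptake genes 2 rose, the glucose transporter SLC2A3 (4.04 ± 0.54) and HK2, none fell and 11 did not pass (2 higher adjusted over the list alone, cameraPR adjusted p = 0.211). Of 15 calcium handling and excitation genes 1 fell, the gap junction gene GJA1 (-1.96 ± 0.44), none rose and 14 did not pass. The list as a whole fell, with a median of -0.69 (5 lower adjusted over the list alone, cameraPR adjusted p = 0.000333). Of 16 cardiac stress and fetal genes 1 rose, NPPA, none fell and 15 did not pass (4 higher and 1 lower adjusted over the list alone, cameraPR adjusted p = 0.0790). All 24 ribosomal protein genes had higher DMVD values and the list rose (median 0.79, cameraPR adjusted p = 1.66e-07), although 0 of the 24 passed one by one, also adjusted over the list alone. Against random lists of like expression, which ignore the correlation between genes, medians lay low for lists that did not pass in cameraPR. The percentile was 0.07 for fatty acid oxidation, 0.17 for the tricarboxylic acid cycle, 0.49 for cardiomyocyte markers and 1.25 for oxidative phosphorylation.

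A further 3 ventricle lists passed in cameraPR at the correlation of 0.01 but not at 0.1. Of 22 interferon-response genes 1 fell, IFIT2 (-2.42 ± 0.65), none rose and 21 did not pass (1 lower adjusted over the list alone, median -0.85, adjusted p = 0.00258, with adjusted p = 0.00332 to 0.0997 over the alternatives). Of 12 Schwann cell and neuronal markers 2 fell, among them the neurotrophin receptor NGFR (-3.31 ± 0.68), none rose and 10 did not pass (4 lower adjusted over the list alone, adjusted p = 0.00592, with adjusted p = 0.010 to 0.0726 over the alternatives). Of 21 nitric oxide and oxidative stress genes 2 rose, the metallothioneins MT2 and MT1 (4.59 ± 0.58), 1 fell, the inducible synthase NOS2 (-4.45 ± 1.21), and 18 did not pass (3 higher and 1 lower adjusted over the list alone, adjusted p = 0.0144, with adjusted p = 0.00321 to 0.526 over the alternatives, the highest with ranks). After the addition of 1 FPKM to both groups MT1 had 3.98, NGFR -1.67, NOS2 -1.02 and IFIT2 -0.81.

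The remaining ventricle lists did not pass in cameraPR at the preset correlation of 0.01. Of 8 adipocyte markers PLIN1 (-4.48 ± 0.79) and CIDEC (-2.86 ± 0.80) fell, RETN (2.56 ± 0.75) rose and 5 did not pass (1 higher and 3 lower adjusted over the list alone, cameraPR adjusted p = 0.0790). Of 14 Wnt signalling genes DKK2 (2.68 ± 0.44) and WNT9B (3.74 ± 0.66) rose, none fell and 12 did not pass (2 higher adjusted over the list alone, cameraPR adjusted p = 0.597). Of 8 mast cell markers SRGN (2.58 ± 0.53) rose, CPA3 (-2.55 ± 0.66) fell and 6 did not pass (1 higher and 3 lower adjusted over the list alone, cameraPR adjusted p = 0.412). A single member rose, and none fell, in each of the lists for chondrogenic and osteogenic genes (SPP1, 2.33 ± 0.62, 1 of 7, 2 higher and 2 lower adjusted over the list alone), hedgehog and valve transcription factors (SNAI1, 2.32 ± 0.60, 1 of 18, 4 higher and 1 lower) and renin-angiotensin and endothelin (EDNRB, 1.87 ± 0.42, 1 of 7, 1 higher and 1 lower). The same held, with counts adjusted over the list alone in the same place, for ketone and branched-chain amino acid metabolism (SLC7A5, 5.61 ± 0.78, 1 of 17, 1 higher), heat shock and unfolded protein response (SDF2L1, 1.64 ± 0.52, 1 of 20, 1 higher) and atrial cardiomyocyte markers (NPPA, 1 of 6, 2 higher and 1 lower). The cameraPR adjusted p values of these lists, from chondrogenic to atrial, were 0.653, 0.330, 0.880, 0.963, 0.211 and 0.512 in that order. Of 3 B and plasma cell markers SDC1 fell and 2 did not pass (1 higher and 1 lower adjusted over the list alone, cameraPR adjusted p = 0.880). No member passed among 9 pericyte markers (2 lower adjusted over the list alone, cameraPR adjusted p = 0.0673, with adjusted p = 0.0375 to 0.213 over the alternatives, the lowest with ranks). Nor did any among 14 antigen presentation genes (cameraPR adjusted p = 0.117), 4 T and NK cell markers (0.136, with adjusted p = 0.0424 to 0.238 over the alternatives, the lowest with ranks), 15 cell cycle genes (0.580) and 19 ubiquitin-proteasome genes (0.606), and 0 passed adjusted over the list alone. The serotonin list had 2 tested members, too few for its own test, of which the serotonin-degrading enzyme MAOA rose by 1.44 ± 0.42 and MAOB had 0.34 ± 0.54. The mitochondrially encoded and the melanocyte lists had 1 tested member each and it did not pass. Against random lists of like expression the percentile of the median was 0.68 for pericyte markers, 0.90 for mast cell markers and 99.03 for T and NK cell markers. It was 92.7 for the metalloprotease and 52.0 for the nitric oxide list, which had passed in cameraPR. List median and test had opposite signs for collagens, Wnt signalling, atrial markers, ketone metabolism, and B and plasma cell markers. Adding 1 FPKM to both groups gave 2.30 for SLC7A5, 1.61 for SNAI1, 1.40 for WNT9B, -1.33 for CIDEC, -1.40 for CPA3 and -2.37 for PLIN1.

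**Figure D1:**
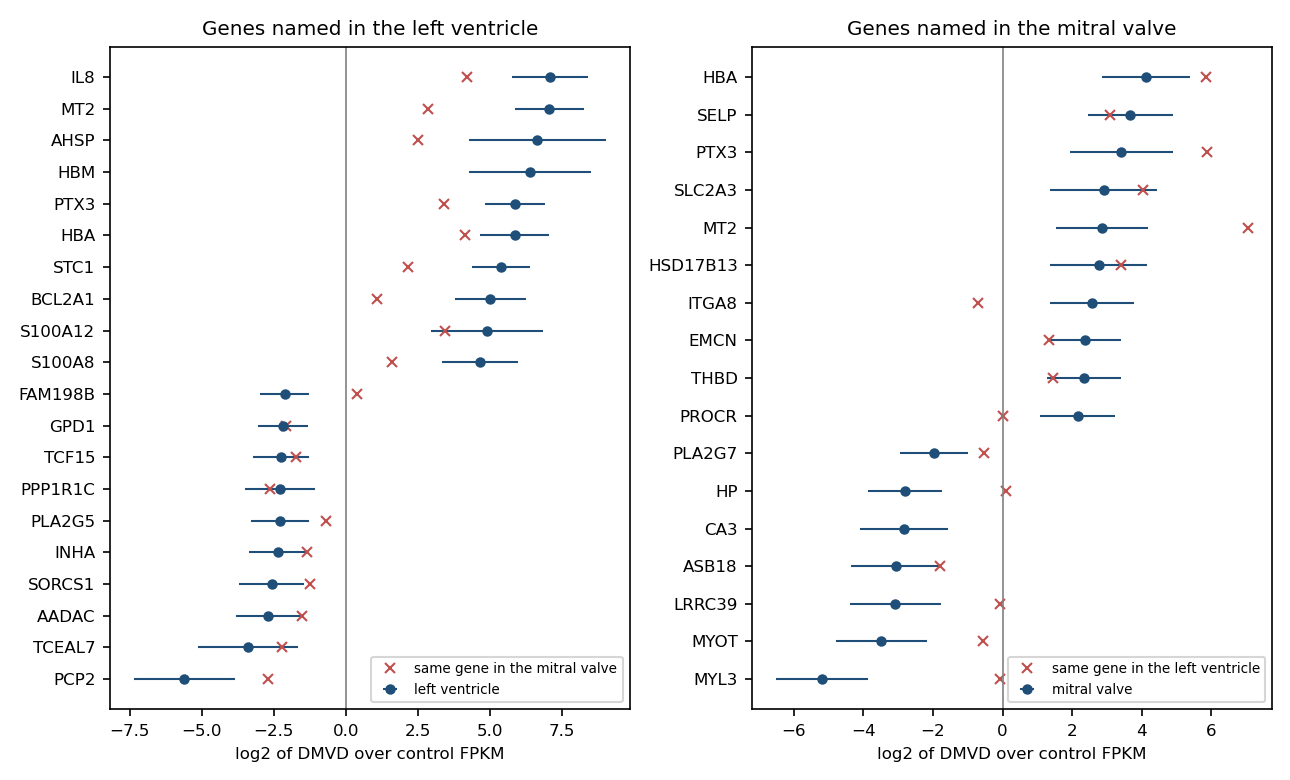
Log2 fold change, DMVD over control, of genes with a symbol and the largest changes past the threshold, at a mean of at least 5 FPKM in the left ventricle and the mitral valve, with bars of 95% around each value from the implied SE and crosses for the same gene in the other tissue where neither of its groups is listed at 0. IL8 at 7.08 and MT2 at 7.07 are the highest values plotted for the ventricle, and MYL3 at -5.19 is the lowest plotted for the valve.

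The test for each gene was the authors' own, on 2 DMVD and 4 control libraries, and the adjustment was made here. In either tissue the list p-values compare genes with other genes and do not measure agreement between dogs. The DMVD and control dogs also differed in breed, and were 5 and 9 years old against 3 to 8. Diagnosis was therefore not separated from breed or age in this tissue.

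The mitral valve comparison asks what differs in the diseased valve samples. These samples also held abundant heart muscle transcripts. The authors' deposited table gave 4523 FPKM of TNNT2 in the control valve and 1846 in the DMVD valve. In the DMVD valve samples, lists of immune and endothelial genes rose and the lists of cardiomyocyte markers and oxidative metabolism fell, while atrial cardiomyocyte markers did not pass. HBA rose by 4.13 ± 0.65 (adjusted p = 5.70e-07), to 604 FPKM against 34.4 in the authors' deposited table. The endothelial and platelet adhesion receptor SELP (ENSCAFG00000015180, chromosome 7, 28956363 to 28997731) rose by 3.67 ± 0.62 (adjusted p = 8.61e-06), and the endothelial anticoagulant receptors THBD and PROCR by 2.34 ± 0.54 and 2.15 ± 0.55. The muscle light chain MYL3 (ENSCAFG00000013618, chromosome 20, 41941315 to 41947260) fell by 5.19 ± 0.68 (adjusted p = 2.64e-10), from 1335 to 36.6 FPKM in the authors' deposited table.

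Of the 14810 genes tested in the valve, 62 passed, 46 higher and 16 lower in DMVD, and 622 had an unadjusted p under 0.05. Of the 62, 16 higher and 8 lower genes had a symbol and a mean of at least 5 FPKM. The 622 were fewer than evenly spread p-values would give, so that number is not read as added signal. In the ventricle the number was above that share, so the numbers of calls in the tissues are not directly comparable. The other large rises were PTX3 (3.41 ± 0.76, adjusted p = 0.00570), SLC2A3 (2.90 ± 0.78, adjusted p = 0.0476), MT2 (2.86 ± 0.68), the lipid droplet protein gene HSD17B13 (2.76 ± 0.71), the integrin ITGA8 (2.57 ± 0.62) and the endothelial sialomucin EMCN (2.37 ± 0.53). The rise of SLC2A3 did not pass with all genes in the adjustment, nor after recentring on the median gene. Further falls were those of the sarcomere and muscle genes MYOT (-3.49 ± 0.67, adjusted p = 0.000298), LRRC39 (-3.09 ± 0.67) and ASB18 (-3.07 ± 0.66), the muscle carbonic anhydrase CA3 (-2.83 ± 0.64), the haemoglobin-binding plasma protein HP (-2.80 ± 0.54) and the phospholipase PLA2G7 (-1.97 ± 0.50). Of the genes named in advance 0 passed: ACTA2 had 1.24 ± 0.54, MYH11 1.20 ± 0.60, EDN1 1.76 ± 0.60 (adjusted p = 0.299), ADAMTS5 1.60 ± 0.80, VCAN 0.89 ± 1.14, COL1A1 0.66 ± 1.06, HAS2 0.26 ± 0.49, NPPB 0.66 ± 1.06 and NPPA -0.05 ± 1.93.

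Immune lists rose in the DMVD valve. Of 25 complement and coagulation genes 3 rose, THBD, the coagulation factor F5 (3.32 ± 0.83) and C1QB (2.12 ± 0.55), none fell and 22 did not pass (10 higher adjusted over the list alone, median 1.35, cameraPR adjusted p = 1.09e-19). Of 16 macrophage and monocyte markers 2 rose, C1QB and S100A9 (3.62 ± 0.97), and 14 did not pass (7 higher adjusted over the list alone). All 16 had higher DMVD values, with a median of 1.65 (cameraPR adjusted p = 1.51e-17), and the scavenger receptor CD163 had 1.99 ± 0.54 (adjusted p = 0.0535). Of 24 cytokine, chemokine and receptor genes 2 rose, IL8 (4.19 ± 0.95) and IL1RL1 (4.10, adjusted p = 0.0177), none fell and 22 did not pass (4 higher adjusted over the list alone, cameraPR adjusted p = 3.29e-14). None of 14 antigen presentation genes passed one by one, but all 14 had higher DMVD values and the list rose (3 higher adjusted over the list alone, median 1.21, cameraPR adjusted p = 4.46e-13). The class II invariant chain CD74 had 2.09 ± 0.63 (adjusted p = 0.129) and DLA-DRA 1.97 ± 0.67. The lists of 8 T and NK cell markers (cameraPR adjusted p = 0.000660) and of 6 B and plasma cell markers (0.00584, with adjusted p = 0.00442 to 0.0912 over the alternatives, the highest with a mean of at least 1 FPKM) rose with 0 members passing, also adjusted over the list alone. Blood transcripts moved with these lists: of 5 erythroid and haemoglobin genes 1 rose, HBA, and 4 did not pass (1 higher adjusted over the list alone, cameraPR adjusted p = 0.000348, with adjusted p = 0.00100 to 0.151 over the alternatives, the highest with ranks). With 1 FPKM added to both groups, IL8 had 2.26, S100A9 1.77, IL1RL1 1.65 and F5 0.96.

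Endothelial, immediate early, signalling and glucocorticoid-response lists also rose in the valve. Of 14 endothelial markers 1 rose, EMCN, none fell and 13 did not pass (2 higher adjusted over the list alone). All 14 had higher DMVD values, with a median of 0.67 (cameraPR adjusted p = 1.76e-08). Of 23 immediate early genes 0 passed (4 higher adjusted over the list alone, median 1.11, cameraPR adjusted p = 7.20e-09), with FOSL2 at 2.36 ± 0.66 and GADD45B at 2.05 ± 0.61. Of 21 TGF-beta and BMP genes 0 passed (1 higher adjusted over the list alone, cameraPR adjusted p = 1.37e-06), with INHBB at 2.51 ± 0.81 and TGFBR2 at 1.26 ± 0.50. Of 21 Wnt signalling genes 0 passed (3 higher adjusted over the list alone, cameraPR adjusted p = 0.000526), with WNT9B at 4.47 ± 1.28 and WNT2 at 2.53 ± 0.83. Of 12 glucocorticoid-response genes 1 rose, MT2, and 11 did not pass (1 higher adjusted over the list alone, cameraPR adjusted p = 0.000620). The 5 serotonin signalling genes tested all had higher DMVD values and the list rose (median 0.76, cameraPR adjusted p = 0.00584) with 0 passing one by one or adjusted over the list alone. They included MAOB (0.76 ± 0.49) and the receptor HTR7 (1.07 ± 0.70).

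A further set of valve lists rose at the preset correlation of 0.01 and did not pass at 0.1. Of 15 smooth muscle and myofibroblast markers 1 rose, the smooth muscle actin ACTG2 (2.03 ± 0.50), none fell and 14 did not pass (1 higher adjusted over the list alone, cameraPR adjusted p = 0.00446, with adjusted p = 0.00390 to 0.0676 over the alternatives). Of 13 fibroblast and valve interstitial cell markers 1 rose, the mucin-type glycoprotein PDPN (2.04 ± 0.48), none fell and 12 did not pass (1 higher adjusted over the list alone, adjusted p = 0.00766, with adjusted p = 0.00678 to 0.0713 over the alternatives). Of 23 elastic fibre and glycoprotein genes 0 passed, also adjusted over the list alone (adjusted p = 0.00179, with adjusted p = 0.00139 to 0.0713 over the alternatives), with THBS1 at 1.52 ± 0.55 and the elastin gene ELN at 1.25 ± 0.48. Of 18 hypoxia-response genes 0 passed (1 higher adjusted over the list alone, adjusted p = 0.00167, with adjusted p = 0.00143 to 0.0550 over the alternatives), and of 6 renin-angiotensin and endothelin genes 0 passed (1 higher adjusted over the list alone, adjusted p = 0.0167, with adjusted p = 0.00440 to 0.123 over the alternatives, the highest with ranks). With 0 members passing in each, the lists of 19 cell cycle genes (adjusted p = 0.0282, with adjusted p = 0.00369 to 0.193 over the alternatives), 19 hedgehog and valve transcription factors (0.0368, and 0.0347 to 0.211), 24 interferon-response genes (0.0368, and 0.0113 to 0.234) and 5 mast cell markers (0.0368, and 0.0178 to 0.125) were in the same position. Adjusted over the list alone, 1 of the transcription factors was higher and 0 genes of the other 3 lists passed.

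Energy metabolism and heart muscle lists fell in the DMVD valve. None of 30 nuclear subunits of oxidative phosphorylation had a higher DMVD value, and the list fell with a median of -0.78 (cameraPR adjusted p = 3.64e-15). The lists of 17 tricarboxylic acid cycle genes (median -0.71, cameraPR adjusted p = 1.76e-08), 26 fatty acid oxidation genes (median -0.68, cameraPR adjusted p = 8.91e-09) and 17 ketone and branched-chain amino acid genes (median -0.74, cameraPR adjusted p = 1.26e-05) fell too. In these 4 lists 0 members passed, also adjusted over the list alone, with the fatty acid genes ACSL1 at -1.36 ± 0.47 and FABP3 at -1.31 ± 0.57. Cardiomyocyte markers moved with them: of 16 tested 1 fell, MYL3, none rose and 15 did not pass. Adjusted over the list alone 1 was lower, and the list fell with a median of -0.96 (cameraPR adjusted p = 4.79e-08). The troponin gene TNNI3 had -1.65 ± 1.12 and the creatine kinase gene CKM -1.52 ± 1.25. Of 7 atrial cardiomyocyte markers 0 passed, also adjusted over the list alone (median 0.19, cameraPR adjusted p = 0.476). Of 17 calcium handling genes 1 fell, the potassium channel KCNJ2 (-4.74 ± 1.22, or -2.20 with 1 FPKM added to both groups), and 16 did not pass (1 lower adjusted over the list alone, cameraPR adjusted p = 0.00446, with adjusted p = 0.00308 to 0.0713 over the alternatives). Of 8 adipocyte markers 0 passed but the list fell (1 higher and 4 lower adjusted over the list alone, median -1.50, cameraPR adjusted p = 1.94e-07), with the lipid droplet coat gene PLIN1 at -2.13 ± 0.59 (adjusted p = 0.0622). Of 19 ubiquitin-proteasome genes 0 passed, also adjusted over the list alone (cameraPR adjusted p = 0.0438, with adjusted p = 0.0360 to 0.230 over the alternatives).

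The collagen, proteoglycan, metalloprotease and chondrogenic lists of the valve did not pass in cameraPR at the preset correlation of 0.01. Of 12 collagens 0 passed, also adjusted over the list alone (median 0.52, cameraPR adjusted p = 0.217). The same was true of 21 proteoglycan and hyaluronan genes (median 0.35, cameraPR adjusted p = 0.0734, with adjusted p = 0.0282 to 0.292 over the alternatives, the lowest with ranks). Of 11 metalloprotease, ADAMTS and TIMP genes 0 passed (1 higher adjusted over the list alone, cameraPR adjusted p = 0.360), with the aggrecanase ADAMTS4 at 2.90 ± 0.89. Of 17 chondrogenic and osteogenic genes 0 passed (1 higher adjusted over the list alone, cameraPR adjusted p = 0.798). MT2 alone rose among 23 nitric oxide and oxidative stress genes (2 higher adjusted over the list alone, cameraPR adjusted p = 0.840). SLC2A3 alone rose among 13 glycolysis genes (1 higher and 1 lower adjusted over the list alone, cameraPR adjusted p = 0.0997, with adjusted p = 0.00878 to 0.277 over the alternatives, the lowest without genes that share a locus). Of 25 ribosomal protein genes 1 fell, none rose and 24 did not pass (1 lower adjusted over the list alone, cameraPR adjusted p = 0.909). With 0 members passing, also adjusted over the list alone, the lists of 8 mitochondrially encoded transcripts (median -1.10, cameraPR adjusted p = 0.0734, with adjusted p = 0.0104 to 0.195 over the alternatives, the lowest with ranks), 9 pericyte markers (0.297), 18 cardiac stress genes (0.683), 20 heat shock genes (0.491) and 12 Schwann cell and neuronal markers (0.840) did not pass at that correlation. The 2 melanocyte markers tested were too few for a list test and did not pass. Against random lists of like expression the percentile of the median was 99.91 for collagens, 99.76 for proteoglycans and 0.04 for mitochondrially encoded transcripts. Among valve lists past cameraPR it was 96.5 for renin-angiotensin and endothelin, 94.0 for hedgehog and valve transcription factors, 91.4 for B and plasma cell markers, 26.2 for ubiquitin-proteasome genes and 3.73 for calcium handling. The pericyte list had a median and a test of opposite signs.

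**Figure D2:**
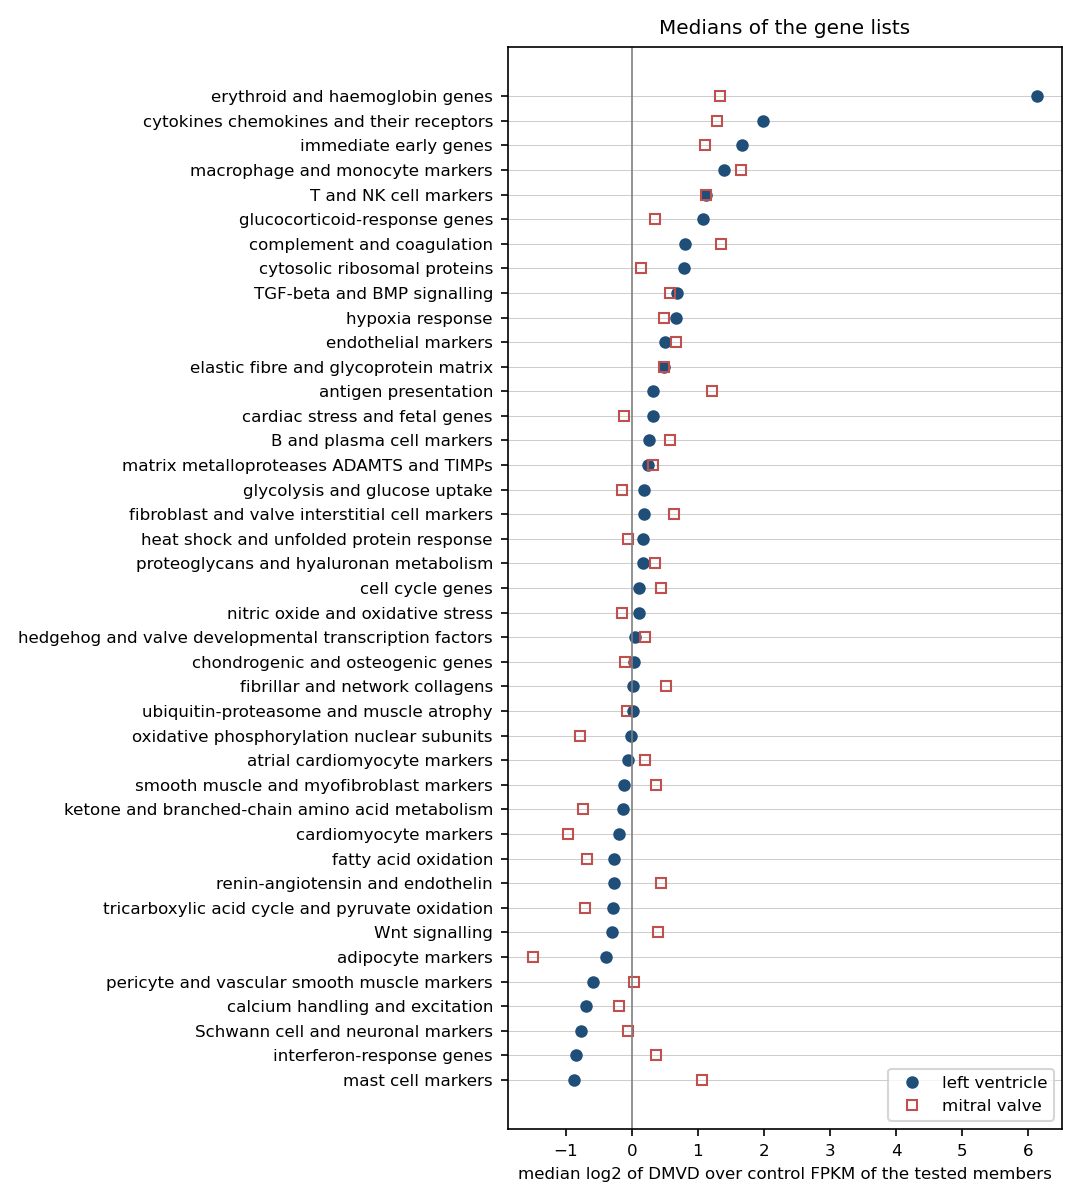
Median log2 fold change, DMVD over control, of each gene list in the left ventricle and the mitral valve, with filled circles for the ventricle and open squares for the valve, for lists with at least 3 tested members in both. The erythroid list at 6.13 in the ventricle is the highest point, and the adipocyte list at -1.50 in the valve the lowest.

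These values rest on 3 DMVD and 3 control libraries and the authors' test. The DMVD dogs were 9 to 17 years old and the control dogs 3 to 8, and the mix of breeds differed. Diagnosis was therefore not separated from age or breed in the valve. The falls of metabolic lists and the rises of other lists were not separated from a smaller share of heart muscle either. The cardiomyocyte list fell beside the metabolic lists, with a median of -0.96.

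Genes called in both tissues ask whether ventricle and valve samples differ in the same way. Of 13333 genes tested in both, 27 were higher in DMVD in both, against 0.758 expected for independent calls (259 called in the ventricle, 39 in the valve, Fisher's exact test, two-sided, p = 4.92e-38). With a symbol these were C1QB, CLDN1, HBA, HSD17B13, IL1RL1, IL8, MT2, PTX3, S100A9, SELP, SLC2A3, SLCO4A1, STC1, THBD and WFDC1. In both tissues 6 genes were lower (152 and 16 called, 0.182 expected, Fisher's exact test, two-sided, p = 1.45e-08), 4 of them with a symbol, ASB18, CA3, GPR162 and TDRD1. Of the 259 genes higher in the DMVD ventricle, 248 had a valve value above 0 (95.8%, against 53.7% of all genes), with a median of 1.10. Of the 152 lower in the ventricle, 122 had a valve value below 0 (80.3%, against 46.3% of all genes), with a median of -0.87. Across 13099 genes, which are not independent replicates, Pearson's r between the log2 fold changes of the tissues was 0.415 and Spearman's rho 0.379. Shared dogs link the comparisons, since 3 control dogs and 1 DMVD dog gave both tissues.

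A direct comparison of the DMVD effects, valve minus ventricle, asks where the tissues part. MYL3 differed by -5.12 ± 0.96 on the log2 scale, with -0.07 ± 0.67 in the ventricle and -5.19 ± 0.68 in the valve. A gene without a symbol in the tables, ENSCAFG00000008524 (chromosome 26, 8623641 to 8632895), chosen after its values were seen, differed by -6.20 ± 1.26. It had -0.73 ± 0.80 in the ventricle and -6.93 ± 0.97 in the valve, where the authors' deposited table gave 15.9 FPKM in DMVD and 1943 in control. MT2 (-4.21 ± 0.91) and STC1 (-3.24 ± 0.75) rose in both tissues, and by less in the valve. The amino acid transporter SLC7A5 (-4.40 ± 0.99) and the deubiquitinase OTUD1 (-3.17 ± 0.76) also had a lower effect in the valve. The extraocular myosin MYH13 (6.61 ± 1.05), OLFML2A (4.51 ± 0.78), the chondroitin sulphate enzyme CSGALNACT1 (3.27 ± 0.72) and CCDC85C (3.93 ± 0.94) had a higher effect in the valve. OLFML2A had -2.42 ± 0.53 in the ventricle and 2.08 ± 0.57 in the valve. Of 13099 genes compared, 14 passed an adjusted p of 0.05 (two-sided normal test of the difference over its SE), 5 with a higher and 9 with a lower effect in the valve, 4 of them without a symbol. By the same test 348 had an unadjusted p under 0.05, fewer than evenly spread p-values would give. MYH13, OLFML2A, CSGALNACT1, SLC7A5 and CCDC85C fall outside the rule for named genes and were chosen after their values were seen. The SE assumes independent tissues, and the median SE of the difference was 0.79. With 1 FPKM added to all groups, the difference became 2.93 for OLFML2A, 2.42 for MYH13, 2.12 for CSGALNACT1, 1.87 for CCDC85C and -1.54 for SLC7A5. The authors' deposited table gave 0.0510 FPKM for MYH13, 0.379 for OLFML2A and 0.234 for CCDC85C in the DMVD ventricle.

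Control values of the tissues, set side by side, describe what each sample holds. The matricellular gene POSTN had 244.6 FPKM in the control valve and 0.453 in the control ventricle in the authors' deposited table. NPPA had 2984 against 12.4 FPKM in the authors' deposited table, and the other genes farthest toward the valve were SFRP4 (log2 ratio 6.99), the cartilage matrix gene COMP (6.96) and SCRG1 (6.91). Farthest toward the ventricle were SPINK4 (-5.71), PCP2 (-4.14), FHIT (-3.49), USMG5 (-2.25) and PPP1R1C (-2.24). Of 19 elastic fibre and glycoprotein genes 17 were more than 4-fold higher in the valve, and the median log2 ratio was 2.35 for collagens, 3.17 for proteoglycans, 2.46 for fibroblast and interstitial cell markers and 4.13 for atrial cardiomyocyte markers. It was -0.64 for cardiomyocyte markers and -0.94 for oxidative phosphorylation subunits. Muscle transcripts of the control valve were abundant, with 4523 FPKM of TNNT2, 1792 of the atrial light chain MYL4 and 1335 of MYL3 in the authors' deposited table. In the DMVD valve the authors' deposited table gave 1846 FPKM of TNNT2, 1631 of MYL4 and 2878 of NPPA. No test was made between tissues, because the tables were normalised separately, and the median of 11498 genes above 1 FPKM in both lay at 0.31 toward the valve.

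**Figure D3:**
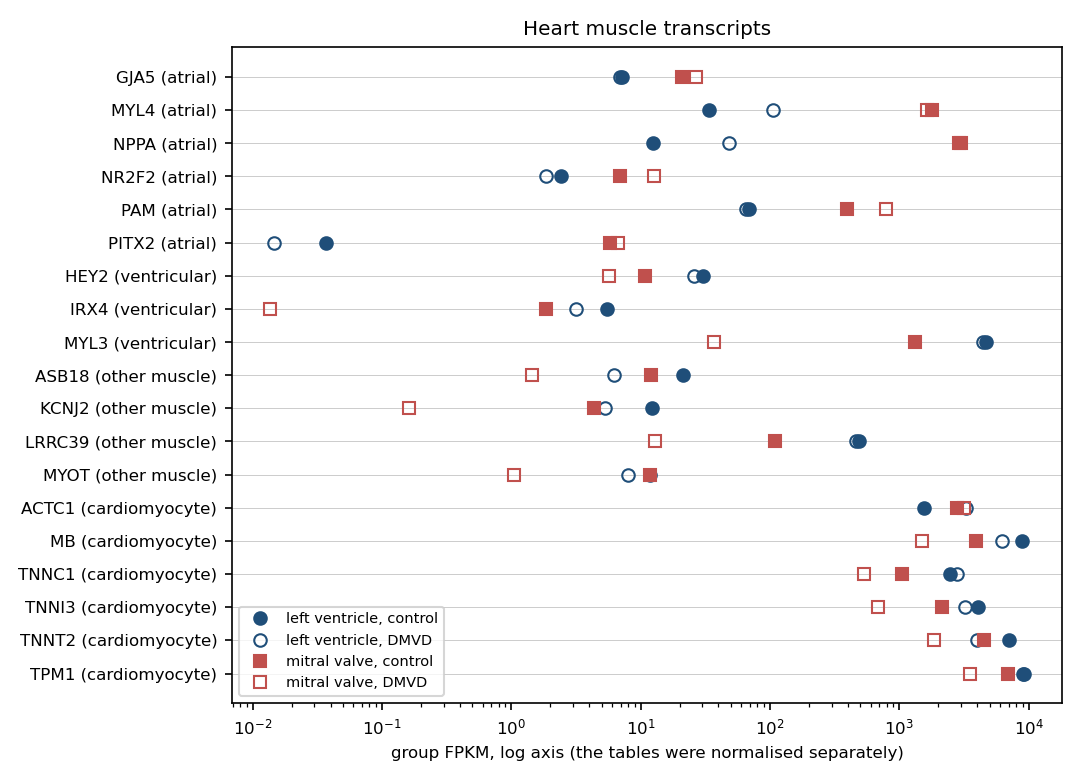
FPKM, on a log axis, of heart muscle genes in the DMVD and control groups of each tissue, as group values of the authors' deposited table without error bars. MYL3 stands at 36.6 in the DMVD valve against 1335 in the control valve, while MYL4 and NPPA lie close together in both valve groups.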

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

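All tests in this part were chosen after the results were seen. The effect of DMVD differed between valve and ventricle, by a test of the difference itself, in 14 genes. Valve minus ventricle on the log2 scale was 6.61 for MYH13, 4.51 for OLFML2A, 3.93 for CCDC85C and 3.27 for CSGALNACT1, and with 1 FPKM added to all groups 2.42, 2.93, 1.87 and 2.12 in the same order. It was -5.12 for MYL3, -4.40 for SLC7A5 (-1.54 with 1 FPKM added), -4.21 for MT2, -3.24 for STC1 and -3.17 for OTUD1. Outside the genes tested, 15 left ventricle genes with too much data for the authors' test were listed at 0 in the control group and above 0 in the DMVD group. Among them the authors' deposited table listed MYH7, the slow myosin heavy chain, at 1637 FPKM and CKM, the muscle creatine kinase, at 6855 FPKM in DMVD. A 0 for such genes may be a placeholder: a further 9 with too much data were listed at 0 in both groups, MT-CO1 among them. The control 0 of MYH7 and CKM is therefore not read as a measured level or as a rise in DMVD.

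MYL3 fell by 5.19 in the DMVD valve, and MYOT, LRRC39 and ASB18 fell with it. ENSCAFG00000008524 fell by 6.93. In the ventricle the authors' deposited table gave it 3754 FPKM in DMVD and 6223 in control. This gene has no symbol in the tables, so it could not be matched to the marker lists. Whether it is one of their members, and so bears on the sources of MYL3 below, was not determined. Less heart muscle of one kind in the DMVD valve samples would lower all its markers alike. MYL3 lay below the median of the other 15 cardiomyocyte markers (-0.96) by a z of -3.24. MYL3 was picked as the only matched marker called, and the z makes no allowance for that, so no conclusion is drawn from it. MYOT (-3.49), LRRC39 (-3.09) and ASB18 (-3.07) lay below the lowest of those markers, TNNI3 (-1.65). Their farthest z was -1.95, with the markers' median SE of 1.12 in it. That test therefore cannot tell these genes apart from less heart muscle of one kind. Ventricular-type muscle in the control valve samples may also be a source of MYL3. The other 3 ventricular markers tested had a median of -1.26 in the valve, and the 7 atrial markers had a median of 0.19. Of these 3, IRX4 had -7.11 ± 2.74 (adjusted p = 0.552 over all genes and 0.0283 over these 3). Its DMVD value was 0.0135 FPKM in the authors' deposited table. The errors of MYH7, IRX4 and HEY2 keep this source open, and age and breed, which differ between the groups, were not tested.

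Haemoglobin transcripts rose in the DMVD ventricle. More blood in the DMVD samples would raise genes made only in red cells alike, but of 5 other members of the list 2 differed from HBA, ALAS2 (z = -5.08) and, farthest, GYPC (z = -9.02). GYPC had -0.91 ± 0.43 (adjusted p = 0.360 over all genes and 0.0337 over the list alone). Whether other cells of the samples made these was not measured, so more blood cannot be told apart from other sources, and a response of the tissue itself was not tested.

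Immediate early transcripts rose in the DMVD ventricle. Scaling of the libraries would move random lists of like expression alike. The list's median stood at percentile 100 of them, 1.70 above the median of all genes. The list was picked after it had passed cameraPR against all other genes, so this percentile was largely fixed in advance. It shows only that the list stood apart from other genes, and no conclusion on scaling is drawn from it. More blood cells in the DMVD samples stay open: the lower of the 95% lower bounds of CTGF and CYR61, genes of matrix-producing and vascular cells, was 0.79, but both were picked among members already called, so this decides nothing. The members called in the ventricle had a median of 1.37 in the valve, 11 of 11 above 0. How the tissue was collected, and age or breed, could each give that and cannot be told apart from the disease, because the labels give no collection times and the groups differ in age and breed.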

How the results depend on the processing

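The alternatives other than the pseudocounts, no filter and the thresholds for the overlap were chosen after the data were seen. No paired analysis was possible because the tables hold group values and the dogs of the groups within a tissue are different animals. No count, called gene or list past the threshold reversed its direction under the alternatives run. For single genes this was largely fixed in advance and says little. Filters and thresholds leave a fold change as it is, and a pseudocount cannot change its sign within a tissue. Lists that did not pass changed sign in cameraPR with ranks, a mean of at least 1 FPKM or without genes that share a locus, and passed in neither direction. In the ventricle these were Wnt, ketone, renin-angiotensin, mast cell, B cell, tricarboxylic acid and oxidative phosphorylation genes, and in the valve metalloprotease, nitric oxide and Schwann cell genes. Pericyte, T and NK cell and proteoglycan lists in the ventricle, and proteoglycan, glycolysis and mitochondrially encoded lists in the valve, passed under 1 of these alternatives each and not at the preset correlation of 0.01; the cause was not tested. At a threshold of 0.01 the left ventricle count was 259, the mitral valve count 30, the difference between tissues 8 and the genes called the same way in both tissues 12, by the construction of a stricter threshold. With a preset correlation of 0.10 the valve lists past the threshold fell from 30 to 19. This follows from the construction of a larger preset correlation, which can only weaken a list. The other alternatives kept the left ventricle count between 364 and 570, the valve count between 50 and 87 and the difference count between 13 and 17. The left ventricle lists stayed between 11 and 16. Of 539 comparisons for 55 named gene values, 517 stayed the same. That meant an unchanged call or, with a pseudocount, where no call was made, a move of less than the SE. The looser threshold of 0.1 could lose no call. Another 12 moved by more than their SE, all with a pseudocount of 1. They were 10 in the ventricle, and SELP at 2.78 and MYOT at -2.64 in the valve. A further 10 kept their direction but not the threshold, 8 of them at 0.01. The others were SLC2A3 in the valve, with no filter and after recentring. A further 72 list members were called in the ventricle and 8 in the valve. A pseudocount of 1 moved 29 and 5 of them by more than their SE. A pseudocount of 0.1 moved 4 and 0, and both results follow from the construction of a pseudocount on low values. Of the differences between tissues, a pseudocount of 1 moved 6 by more than their SE, and a pseudocount of 0.1 moved MYH13 alone (5.06). Not run, for want of values per library, were other normalisations and count models, each library left out in turn, the block by label number, age as a covariate, beagles only, the joint fit of 12 libraries, an estimated correlation, fry and other splits of the samples. Depth is unknown and limits genes of low value most.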

Other observations

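The mitochondrial genome held 13 short loci without a symbol, each under 100 bases long and tested in both tissues. In the DMVD ventricle 8 of them were lower past the threshold, with log2 fold changes from -3.42 to -1.64. In the DMVD valve 0 passed, with a median of -1.43 and 11 of the 12 with a fold change below 0; the difference between tissues was not tested for these loci as a set. The mitochondrially encoded protein genes were mostly untested in the ventricle because their data passed the authors' upper limit.

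The Xist_exon4 locus on chromosome X was listed in the authors' deposited table at 0 FPKM in the DMVD ventricle and 209.1 FPKM in the control ventricle (adjusted p = 0.0837), and at 67.7 and 363.4 FPKM in the DMVD and control valve, where it did not pass. The sexes of the dogs are not among the labels used here, so sex was not separated from diagnosis either.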
